A study of Mus musculus with 4 samples.

How the data were processed

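Gene expression was measured in the lumbar spinal cord of 4 adult male ICR mice, an outbred strain, at 10 days after surgery. The labels' protocol names the L4 to L5 segments and the labels' source field L5 cord only. The side of the cord that was taken is not given in the sources used here. In 2 mice the L5 spinal nerve was tied tightly (spinal nerve ligation, SNL), and in 2 mice the nerve was exposed and left untied (sham). Per the labels' protocols the replicates are separate mice, and each gave 1 RNA sample and 1 array, so every p-value rests on 2 mice per group. Per the labels' protocols, total RNA was amplified and labelled with the dye Cy3 and hybridised to 1-colour Agilent arrays. The deposited scanner files hold spot intensity values on a linear scale made with Agilent Feature Extraction, and per the file headers' column names these are processed signals in which dim spots carry a surrogate value. The version is 10.7.3.1 per the file headers and 10.7.1.1 per the submitters' processing notes. Per the file headers, the array is design 028005 and its probe positions refer to the mouse build mm9. No genome sequence was used here. A table of log2 values deposited by the authors for the whole series was used as an alternative. Set against each array's own scanner values, its columns had a correlation that rounds to 1, so they hold the same log2 scale, shifted to about each array's 75th percentile and not centred per gene, and a higher value is a brighter spot. Its columns lie 0.122 to 0.132 from the values used here in the median, and over which spots that percentile was taken stays unknown. Its column medians were -3.45 and -3.52 for the sham arrays and -3.48 and -3.33 for the SNL arrays.

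The main values were log2(processed signal) minus each array's 75th percentile over 59305 non-control spots. Spots flagged as outliers were left out, and spots of one probe were averaged. Of 55681 probes, 26762 took a current gene symbol through their accession, 3819 through a current symbol and 639 through a synonym in a RefSeq gene table. The other 24461 kept the name in the file, and 16194 of these are long intergenic RNA probes named by region. A probe entered the test if it was well above background on at least 2 of the 4 arrays, and a gene with several probes was represented by the probe with the highest mean over the 4 arrays. This left 29114 genes and named transcripts. A gene well above background on neither array of a group has only a bound there, and where 1 of the 2 arrays measured it the fitted change is given with that number. The fold of a gene with a bound is given as at least the brighter group's mean over the higher of 2 signals, array by array. These are the dim probe's own signal and the lowest signal among probes well above background. As the lowest such signal is used, the bound holds for the main values only, and normexp correction gave smaller folds for most named genes with a bound. With these bounds no list median moved.

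SNL was compared with sham in limma 3.58.1 under R 4.3.3, with lmFit and eBayes and no covariate, and fold changes are SNL minus sham on the log2 scale. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors are SE of the fold change or SD between 2 mice. The fit had 2 residual degrees of freedom and 1.66 from the prior. An exact two-sided permutation test of 2 against 2 mice cannot go below p = 0.333, so none is given. Because few genes were likely to pass, genes changed at least 2-fold at unadjusted p under 0.05 were counted too. The number of arrays limits the precision, and the median SE over genes was 0.13. The planned block for slide or scan was not possible with 1 slide and 1 scan.

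A set of 40 gene lists was fixed before the data were examined, covering microglia, immune signalling, astrocytes, oligodendrocytes and their precursors, neurons, motor neurons, axon injury, transmission, ion channels, sensory ganglia, Schwann cells, vessels, meninges, ependyma, blood cells, muscle, stress responses, Hox genes and housekeeping genes. They hold 758 genes, of which 728 were tested. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over their list alone. Named genes were chosen by a rule set before the data were examined. It took the 12 largest increases and 8 largest decreases among called genes whose groups did not overlap, filled where needed from 2-fold changes at unadjusted p under 0.05 whose groups did not overlap, and left out names of predicted genes. It added up to 4 members with the smallest p of each described list, and 12 genes long studied in this tissue. Of these 12, Cxcr5 was not well above background on enough arrays to be tested. Other genes are said to have been chosen after their values were seen, and which members with the smallest p are printed was also settled then. Some genes that this rule takes are not reported here.

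The fit was tested on simulated data with the real means of the 29114 genes, in which 200 genes were changed. Noise was normal, with variances drawn at random from the prior that the fit estimated, with a cap, and not taken gene by gene. The fit called 0 of 50 genes changed by 1 on the log2 scale, 30 of 50 changed by 2, 46 of 50 changed by 4 and 46 of 50 changed by 6, with 3 calls among unchanged genes. Such data largely meet the fit's own assumptions, so these 3 calls do not show how often unchanged genes are called in the real data. Camera with the preset correlation called a list shifted by 1 and 0 of 36 lists that share no member with it. The simulated genes were drawn independently, while correlations estimated in the real lists reached 0.90. The simulation therefore does not show how often camera with the preset correlation calls unchanged lists in the real data. With an estimated correlation 0 lists were called in that simulation, the shifted one included, and fry gave the shifted list an adjusted p of 0.0355.

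Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of detected probes, the deposited value table, no filter on dim probes, a filter on all 4 arrays, removal of saturated probes, the mean of a gene's probes, every probe tested alone, a variance trend with robust estimation, the replicate number as a block, each mouse left out in turn, and flagged spots kept. All 4 arrays lay on 1 slide and were read in 1 scan. The sham arrays occupied slide row 1 and the SNL arrays slide row 2, so slide row and group cannot be told apart.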

Results

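The data are 4 whole-genome expression arrays of lumbar spinal cord, 2 from mice with a ligated L5 spinal nerve and 2 from sham-operated mice, all taken at day 10. Ligation of this nerve is a standard model of neuropathic pain, and the comparison asks which transcripts differ in the cord that receives the injured nerve. Of the spots, 82.1% and 81.9% were well above background on the sham arrays, against 74.9% and 78.1% on the SNL arrays. The surrogate for dim signals was used for 5136 and 5195 spots on the sham arrays and for 7878 and 6515 on the SNL arrays. No spot was saturated on any of the 4 arrays. Across genes, which are not independent replicates, the 2 sham arrays correlated at r = 0.991, the 2 SNL arrays at r = 0.988, and arrays of different groups at 0.982 to 0.984.

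Among genes that passed, the largest increases after ligation included Atf3, a transcription factor induced by axon damage, which rose by 5.22 ± 0.10 on the log2 scale (SE, n = 2 per group, adjusted p = 0.0371), or 37.2-fold. Gpr151, an orphan receptor, rose 35.2-fold (5.14 ± 0.26, adjusted p = 0.0475). The cornified envelope genes Sprr2j-ps and Sprr1b, the muscle ankyrin repeat gene Ankrd1, the keratin Krt16, the lipase Lipn, Sprr2f and the proteoglycan Kera were not well above background in either sham mouse. They were at least 55.8-fold, 18.5-fold, 43.2-fold, 19.2-fold, 29.7-fold, 7.07-fold and 6.01-fold higher after ligation, with adjusted p from 0.0371 to 0.0475. With normexp correction, 5 of these log2 changes moved by over 1.5 times, to 4.67 for Sprr2j-ps, 3.55 for Sprr1b, 3.55 for Krt16, 2.62 for Sprr2f and 2.26 for Kera. Ankrd1 and Lipn were then at 4.39 and 3.76. For each of these genes the fold with normexp correction was below the bound given, so the bounds hold for the main values only. Speer1 and Speer4d rose by 5.70 ± 0.24 and 5.69 ± 0.26, and Speer3, which was well above background in 1 of 2 sham mice, by 4.74 ± 0.19. Another probe of Speer4d gave 3.56, and without SNL replicate 1 the gene was at 3.25. Sprr1a, an injury-induced gene chosen after its values were seen, was at 8.97 ± 1.59 and did not pass (adjusted p = 0.208), with sham values of -8.27 and -3.98. Sprr and Speer genes belong to families of similar sequence, so which member each probe reads is uncertain.

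Among decreases, 3 genes passed. Mnx1, a homeobox factor of motor neurons, was at least 15.6-fold lower after ligation and was not well above background in either SNL mouse (adjusted p = 0.0402). Its fitted change was -3.07 with normexp correction, a smaller fall than that bound. Chodl, a marker of fast motor neurons, fell by 3.84 on the log2 scale (SE 0.12, adjusted p = 0.0371), or 14.3-fold, and the potassium channel gene Kcnj14 fell by 3.17 (SE 0.12, adjusted p = 0.0402). Next by size among decreases of at least 2-fold at unadjusted p under 0.05, with groups that did not overlap, were 5 genes that did not pass: Uts2b at -2.99, Gnb3 at -2.98, Vipr2 at -2.96, Spp2 at -2.92 and Prok1 at -2.90, with adjusted p from 0.0668 to 0.117. These 5 passed with no filter on dim probes and with a variance trend and robust estimation. Gnb3 was well above background in 1 of 2 SNL mice and Prok1 in neither, where it was at least 2.88-fold lower, with a fitted change of -1.56 after normexp correction. On mm9, the probe of Atf3 lies on chromosome 1 at 192994547 to 192994606, that of Mnx1 on chromosome 5 at 29799801 to 29799860, and that of Chodl on chromosome 16 at 78951190 to 78951249. Their place within exons was not analysed here.

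**Figure D1:**
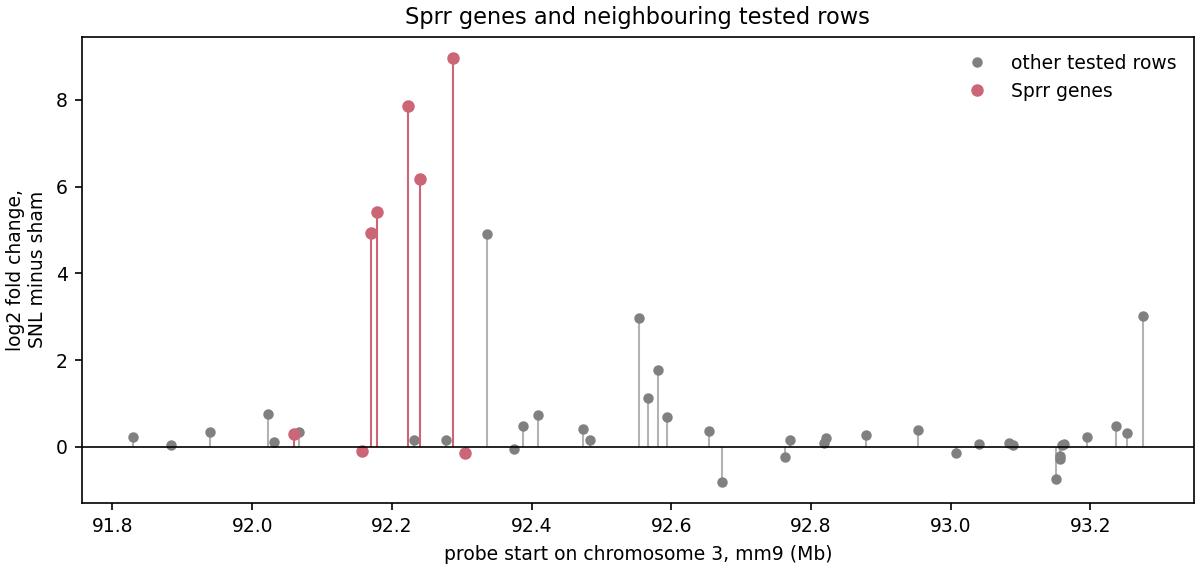
Log2 fold change, SNL minus sham (y axis), of tested probes by position on chromosome 3 of mm9 in Mb (x axis), with red points for Sprr genes and grey points for other genes or named transcripts. Fitted values, with no bound applied, are 8.97 for Sprr1a, 7.85 for Sprr2j-ps, 6.18 for Sprr1b, 5.41 for Sprr2g (2.90 with normexp correction), 4.93 for Sprr2f and 3.01 for Tchhl1, of which Sprr1a, Sprr2g and Tchhl1 were chosen after their values were seen.

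In all, 47 genes or named transcripts were higher and 3 lower in SNL at adjusted p under 0.05 in limma, of 29114 tested. Current gene symbols are carried by 34 of the higher and all 3 of the lower, and 6 of the higher are long intergenic RNA regions. At unadjusted p under 0.05, 1942 were higher and 1595 lower, against 1455.7 expected by chance in both directions together. At least 2-fold changes at that p numbered 557 higher and 208 lower. The groups did not overlap for 45.8% of genes, against 33.3% by chance. With quantile normalization the called genes were 11 higher and 0 lower, and leaving out any 1 of the 4 mice left 0 in each direction, with 531 to 773 genes higher and 117 to 557 lower by 2-fold at unadjusted p under 0.05. The share of 2-fold changes that were higher was 72.8%, against 84.6% with normexp correction, 86.4% without sham replicate 1 and 55.4% without SNL replicate 2. Of the 40 fixed lists, camera with its preset correlation called 18 higher and 4 lower, and 0 were called with an estimated correlation (lowest adjusted p = 0.472). Fry, which asks whether a list's genes move one way on balance, called 6 higher and 0 lower: the microglia core, cytokine, axon injury, immediate early, T and NK cell and glucocorticoid lists.

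**Figure D2:**
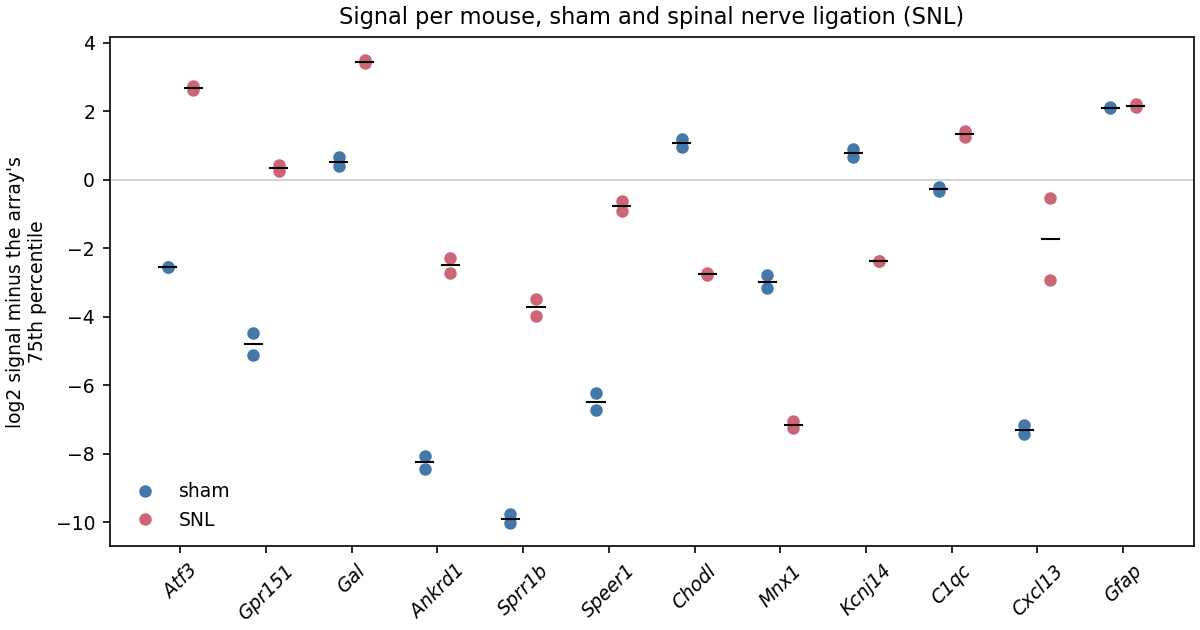
Log2 signal minus each array's 75th percentile (y axis) for 12 genes (x axis), with 1 point per mouse and a bar at the mean of 2 sham or 2 SNL mice. Atf3 lies at -2.54 and -2.55 in sham and at 2.74 and 2.60 in SNL mice, while Chodl lies at 1.18 and 0.97 in sham and at -2.73 and -2.79 in SNL mice.

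Genes of axon injury and regeneration rose as a list, with a median log2 change of 0.51 over 27 measured members (camera adjusted p = 7.56e-12, and adjusted p = 0.472 with an estimated correlation). Atf3, Gpr151 and the neuropeptide gene Gal, which rose by 2.92 ± 0.14 (adjusted p = 0.0475), passed over all genes. Adjusted over the list alone, 11 were higher and 0 lower. Sox11, a growth-associated transcription factor, was at 1.27 ± 0.088 and the neuropeptide gene Npy at 1.94 ± 0.22, which did not pass over all genes. The motor neuron list fell, with a median of -0.47 over 17 members (camera adjusted p = 1.27e-09, and adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone, 9 members were lower and 0 higher, and over all genes 2 were lower, Mnx1 and Chodl. Values lay above 0 for 3 of the 17. Uts2, the urotensin gene, was at -2.19 ± 0.12 and Calcb, a calcitonin gene-related peptide gene, at -2.47 ± 0.16, with adjusted p of 0.0509 and 0.0668 over all genes. Chat, which makes acetylcholine, was at -0.73 ± 0.14 and its vesicular carrier Slc18a3 at -0.36 ± 0.12, both chosen after their values were seen, and Slc18a3 at -0.62 with normexp correction.

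The microglia and macrophage core list rose, with a median log2 change of 0.93, or 1.90-fold, over 28 members (camera adjusted p = 1.41e-22, and adjusted p = 0.472 with an estimated correlation). Adjusted over the list alone, 27 members were higher and 0 lower, and over all genes 0 passed. The complement chains C1qc, C1qb and C1qa were at 1.61 ± 0.11, 1.51 ± 0.12 and 1.28 ± 0.12, and the surface protein gene Cd48 at 1.17 ± 0.095. Irf8, a transcription factor of microglia, was at 1.00 ± 0.15, Csf1r, the receptor that maintains microglia, at 0.54 ± 0.14, Aif1 at 0.52 ± 0.15 and Itgam at 0.33 ± 0.12. Itgam was at 0.14 with quantile normalization, 0.21 without SNL replicate 1 and 0.77 as the mean of its probes, its probes ranged from 0.33 to 1.02, and the 3 detected probes of Csf1r differed in sign, from -0.075 to 0.88.

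Homeostatic microglia genes rose with a median of 0.48 over 14 members (camera adjusted p = 8.73e-05, and adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone, 4 were higher and 0 lower, against 0 over all genes, and Tmem119, Cx3cr1 and Gpr84 were at 0.79 ± 0.11, 0.57 ± 0.12 and 1.33 ± 0.30. The other 10 members did not pass over the list alone, and 1 of them, Sall1 at -0.30, was lower at unadjusted p under 0.05 in limma. P2ry12 was at 0.26 and Siglech at 0.056, and these and Sall1 were named after their values were seen. Values lay above 0 for 13 of the 14 members. Without SNL replicate 1 the list's median was 0.27, and with normexp correction Cx3cr1 was at 0.34. Disease-associated microglia genes rose with a median of 0.41 over 19 members (camera adjusted p = 1.25e-06, and adjusted p = 0.501 with an estimated correlation). By p adjusted over the list alone, 5 were higher and 0 lower, against 0 over all genes. Cst7, a cathepsin inhibitor, was at 2.51 ± 0.20, Itgax at 2.12 ± 0.27, Gpnmb at 1.11 ± 0.13, the lysosomal marker Cd68 at 0.88 ± 0.12 and, named after its value was seen, Lgals3 (2.15-fold). Genes of microglial pain signalling rose with a median of 0.40 over 23 members (camera adjusted p = 2.42e-06, and adjusted p = 0.472 with an estimated correlation). Counting members by p adjusted over the list alone, 9 were higher and 0 lower, against 0 over all genes, and Tlr7, Irf5 and the nucleotide receptor P2ry6 were at 1.62 ± 0.17, 0.85 ± 0.11 and 1.15 ± 0.16. P2rx4, an ATP-gated channel, was at -0.063 ± 0.091 and the growth factor Csf1 at 0.40 ± 0.12, and Csf1 was at 0.84 as the mean of its probes. With normexp correction Irf5 was at 0.51 and P2rx4 at -0.20, and P2rx4 was at -0.21 as the mean of its probes. Without sham replicate 2 and without SNL replicate 2, P2rx4 was at -0.039 and -0.038.

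**Figure D3:**
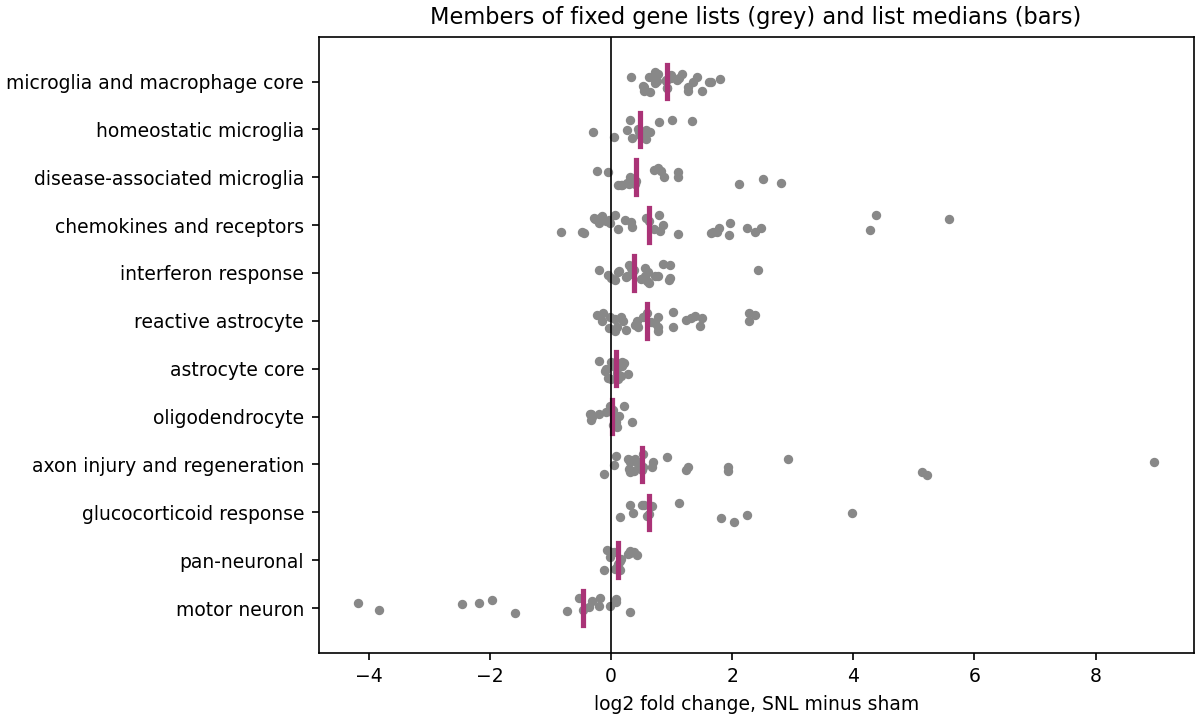
Log2 fold change, SNL minus sham (x axis), of the measured members of 12 fixed gene lists (y axis), with 1 grey point per gene and a bar at each list's median. The median is 0.93 for the microglia and macrophage core, 0.081 for the astrocyte core and -0.47 for the motor neuron list.

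Chemokines and their receptors rose as a list, with a median of 0.63 over 35 members (camera adjusted p = 0.000107, and adjusted p = 0.487 with an estimated correlation). Of its members, adjusted over the list alone, 11 were higher and 1 lower, and over all genes 0 passed. The lower one, named after its value was seen, was the scavenging receptor gene Ackr3 at -0.44 ± 0.11, or -0.21 with normexp correction. Ccl8, Ccl7 and Ccl5, which attract monocytes and lymphocytes, were at 4.38 ± 0.35, 4.27 ± 0.55 and 2.47 ± 0.22. Cxcl13, which attracts B cells, had the largest value of the list, 5.57 ± 0.90, with an adjusted p of 0.186 and SD of 1.70 between the 2 SNL mice. Ccl2 was at 1.94 ± 0.37 and Cxcl10, an interferon-induced chemokine, at 2.37 ± 0.36.

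Cytokines and inflammatory mediators rose with a median of 0.41 over 30 members (camera adjusted p = 6.05e-07, and adjusted p = 0.472 with an estimated correlation). With p adjusted over the list alone, 12 were higher and 0 lower, against 0 over all genes. The tumour necrosis factor receptor gene Tnfrsf1b was at 1.35 ± 0.12, Il1a at 1.47 ± 0.20 and Nfkbia, an inhibitor of NF-kB, at 0.68 ± 0.094, while Il6 was not well above background in sham mice and at least 3.37-fold higher. Interferon response genes rose with a median of 0.37 over 27 members (camera adjusted p = 1e-08, and adjusted p = 0.472 with an estimated correlation). By p adjusted over the list alone, 11 were higher and 0 lower, against 0 over all genes. Irf7, Oasl2, Mx1 and Usp18 were at 0.97 ± 0.12, 0.73 ± 0.093, 2.42 ± 0.36 and 0.97 ± 0.14. With normexp correction Mx1 was at 1.39, and the fitted change of Il6 was 1.07 against 1.92.

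Complement genes rose with a median of 0.43 over 18 members (camera adjusted p = 0.00961, and adjusted p = 0.726 with an estimated correlation). Counting members by p adjusted over the list alone, 4 were higher and 1 lower, against 0 over all genes. The higher ones were C1qa, C1qb, C1qc and, named after its value was seen, the receptor gene C3ar1 at 1.59 ± 0.28, and the lower one was Cd55, which limits complement activation, at -0.97 ± 0.096. Antigen presentation genes rose with a median of 0.34 over 18 members (camera adjusted p = 0.0322, and adjusted p = 0.726 with an estimated correlation). Of its members, adjusted over the list alone, 0 passed, as over all genes, and B2m and Psmb9 were at 0.36 ± 0.10 and 0.41 ± 0.11. T and NK cell genes rose with a median of 0.16 over 19 members (camera adjusted p = 0.00951, and adjusted p = 0.472 with an estimated correlation). With p adjusted over the list alone, 4 were higher and 0 lower, against 0 over all genes, with Ms4a4b at 1.37 ± 0.11, Cd3e at 0.87 ± 0.17, Il2rb at 0.93 ± 0.19 and Cd8b1, which was not well above background in sham mice, at least 3.22-fold higher. Without SNL replicate 1 none of these 3 list calls was kept (medians 0.41, 0.15 and 0.21), and without sham replicate 2 the complement and antigen presentation calls ended (0.20 and 0.082), as they did with no filter on dim probes (0.54 and 0.34). Complement medians per mouse were -0.23 and -0.91 in sham and -0.23 and -0.23 in SNL, and without sham replicate 1 the list was at 0.99. Antigen presentation medians per mouse were -0.22 and -0.78 in sham and -0.26 and -0.38 in SNL, so sham replicate 1 lay above both SNL mice. The T and NK cell median was 0.27 with normexp correction and 0.32 and 0.30 without sham replicates 1 and 2, and that correction put Psmb9 at 0.18 and the fitted change of Cd8b1 at 1.45 against 2.97.

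Reactive astrocyte genes rose with a median of 0.60 over 31 members (camera adjusted p = 8.11e-08, and adjusted p = 0.501 with an estimated correlation). By p adjusted over the list alone, 10 were higher and 0 lower, against 0 over all genes. Without sham replicate 2 the median was 0.35, and medians per mouse were -0.35 and -1.08 in sham and -0.20 and -0.27 in SNL. The transporter gene Slc10a6 was at 1.51 ± 0.12, with 5.01 for another probe and 3.26 for the mean of both, Serpina3n, a protease inhibitor, at 1.23 ± 0.11, Aspg at 1.32 ± 0.13 and Timp1, which inhibits matrix proteases, at 2.28 ± 0.33. Gfap, the astrocyte filament gene of this list, was at 0.060 ± 0.096 (adjusted p = 0.843) and at -0.16 with normexp correction, 0.0092 with quantile normalization, 0.10 as the mean of its probes and 0.011 to 0.11 with 1 mouse left out. The astrocyte core list had a median of 0.081 over 16 members and was not called (camera adjusted p = 0.405), with 0 members past the threshold adjusted over the list alone and 0 over all genes.

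Oligodendrocyte precursor genes fell with a median of -0.13 over 12 members (camera adjusted p = 0.0268, and adjusted p = 0.6 with an estimated correlation). Counting members by p adjusted over the list alone, 1 was lower, C1ql1 at -0.77 ± 0.092, and over all genes 0 passed. Endothelial and mural genes fell with a median of -0.22 over 21 members (camera adjusted p = 0.00468, and adjusted p = 0.655 with an estimated correlation), with 0 members past adjusted over the list alone and 0 over all genes. Cell cycle genes fell with a median of -0.17 over 28 members (camera adjusted p = 0.00961, and adjusted p = 0.472 with an estimated correlation), also with 0 past adjusted over the list alone and 0 over all genes. The precursor and endothelial calls ended without sham replicate 1 (-0.038 and -0.18), and the precursor and cell cycle calls without SNL replicate 2 (-0.042 and -0.16). Normexp correction ended the cell cycle call too (-0.075), and moved the precursor and endothelial medians to -0.26 and -0.11. In the other direction, the lowest precursor median with 1 mouse left out was -0.23.

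Dorsal horn neuropeptide and receptor genes rose with a median of 0.16 over 33 members (camera adjusted p = 0.0211, and adjusted p = 0.726 with an estimated correlation). Of its members, adjusted over the list alone, 4 were higher and 1 lower, and over all genes 1 was higher, Gal. The lower one, named after its value was seen, was the peptide gene Cartpt at -0.51 ± 0.090. Npy is given above, the receptor gene Calcrl was at 1.52 ± 0.19 and Crh, corticotropin-releasing hormone, at 2.10 ± 0.28. Immediate early genes rose with a median of 0.22 over 25 members (camera adjusted p = 0.016, and adjusted p = 0.487 with an estimated correlation). With p adjusted over the list alone, 2 were higher, Atf3 and Fosl1 (2.14-fold), and over all genes 1, Atf3. Pan-neuronal genes rose with a median of 0.12 over 17 members (camera adjusted p = 0.0424, and adjusted p = 0.726 with an estimated correlation), with 0 past adjusted over the list alone and 0 over all genes. Without SNL replicate 1 none of these 3 list calls was kept (medians 0.20, 0.21 and 0.097), nor with normexp correction (0.15, 0.18 and 0.15). The neuropeptide and pan-neuronal calls also ended without sham replicate 1 (0.045 and 0.063), the immediate early call without sham replicate 2 (0.21), and the pan-neuronal call with quantile normalization (0.0096), the median of detected probes (0.095), the mean of a gene's probes (0.080), single probes (0.071) and the filter on all 4 arrays (0.12). With no filter on dim probes all 3 calls ended (0.16, 0.23 and 0.12), and with quantile normalization the neuropeptide median was 0.089. In the other direction, the neuropeptide median was 0.29 without sham replicate 2 and the pan-neuronal median 0.18 without SNL replicate 2, and Fosl1 was at 0.68 with normexp correction against 1.1.

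Glucocorticoid response genes rose with a median of 0.63, or 1.54-fold, over 13 members (camera adjusted p = 6.33e-11, and adjusted p = 0.472 with an estimated correlation). By p adjusted over the list alone, 11 were higher and 0 lower, against 0 over all genes. Plin4, a lipid droplet coat gene, was at 3.97 ± 0.28, Cdkn1a, a cell cycle inhibitor, at 2.25 ± 0.19, Pdk4, a kinase that limits glucose oxidation, at 1.81 ± 0.11 and Zbtb16 at 1.12 ± 0.13. The 3 detected probes of Cdkn1a ranged from 0.0059 to 2.25, with a mean of 1.48. Lysosome genes rose with a median of 0.21 over 25 members (camera adjusted p = 1.09e-05, and adjusted p = 0.592 with an estimated correlation), with 7 higher and 0 lower adjusted over the list alone and 0 over all genes, among them the protease gene Ctss at 0.69 ± 0.11. Housekeeping genes rose with a similar median, 0.22 over 12 members (camera adjusted p = 0.00495, and adjusted p = 0.501 with an estimated correlation), with 0 past adjusted over the list alone and 0 over all genes. The pan-neuronal, T and NK cell, neuropeptide and immediate early medians (0.12, 0.16, 0.16 and 0.22) did not exceed the housekeeping median. Actb was at 0.48 ± 0.10 and Gapdh at 0.25 ± 0.11, or 0.21 and 0.14 with normexp correction and 0.29 and 0.076 with quantile normalization. The housekeeping median was 0.12 with quantile normalization, where the call ended, as it did with normexp correction (0.21) and without SNL replicate 1 (0.22), and it was 0.15 without sham replicate 1.

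For lists not called by camera (adjusted p from 0.0563 to 0.988) the medians are given, and members passed adjusted over the list alone only in the 3 lists said to hold one. Neuronal lists were GABA and glycine transmission at 0.028, glutamate transmission at -0.030, ion channels at 0.029 and dorsal root ganglion sensory neurons at 0.040, in which 1 member, Isl2, was lower adjusted over the list alone (-1.27 ± 0.12) and 0 over all genes. Oligodendrocyte genes were at 0.019, ependymal genes at 0.24, B cell genes at -0.33, cholesterol synthesis at -0.0069 and heat shock at 0.074. Among these, Cyp51 of cholesterol synthesis was lower adjusted over the list alone (-0.74 ± 0.092) and not over all genes. The rostral and caudal Hox lists, which mark the level of the cord, were at -0.034 and 0.028. The rostral Hox list was called lower without sham replicate 1 (-0.13) and without SNL replicate 1 (-0.035). Glutamate transmission was called lower without sham replicate 1 (-0.16), with normexp correction (-0.065), with the filter on all 4 arrays (-0.030), with the mean of a gene's probes (-0.10) and over single probes (-0.10). Neutrophil and monocyte genes were at -0.44, and 1 member, Il1r2, was higher adjusted over the list alone (0.78 ± 0.11) and 0 over all genes. That list was called lower without sham replicate 1 (-0.75), without SNL replicate 1 (-0.76), with normexp correction (-0.58), and with no filter or the filter on all 4 arrays (-0.44 in both), and was at -0.096 without SNL replicate 2. Also called lower were oligodendrocyte genes with quantile normalization (-0.11), GABA and glycine transmission over single probes (-0.067) and cholesterol synthesis without SNL replicate 1 (-0.071). The astrocyte core list was called higher without SNL replicate 2 (0.19), and ependymal genes were called lower without sham replicate 1 (-0.40) and higher without sham replicate 2 (0.50). For the oligodendrocyte, GABA and glycine, ion channel, sensory neuron, erythroid and caudal Hox lists, the median and camera's direction differed in sign.

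For markers of other tissues, values are given per mouse. The skeletal muscle list had medians of -3.06 and -2.17 in the sham mice and of 1.00 and -3.34 in the SNL mice, and the Schwann cell list had -0.37 and -2.99 in the sham mice and -0.095 and -0.75 in the SNL mice. The meningeal fibroblast list stood at 0.49 and -0.76 in the sham mice and at 0.50 and 0.013 in the SNL mice, the perivascular macrophage list at -2.18 and -4.0 against -2.37 and -2.21, and the erythroid list at -1.45 and -0.22 against -1.34 and -1.79. None of these 5 lists was called between groups, with log2 medians of 0.91, 0.79, 0.20, 0.61 and 0.0015. Leaving out 1 mouse turned the direction of each of these lists and gave calls. The muscle list was called lower without SNL replicate 1 (-1.44) and higher without SNL replicate 2 (3.59). Without sham replicate 1 the Schwann cell, meningeal and perivascular lists were called higher (2.04, 0.93 and 1.28) and the erythroid list lower (-0.46). Without sham replicate 2 these 4 medians were -0.26, -0.31, -0.31 and 0.47, and the meningeal list was called lower. The Schwann cell and meningeal lists were also called higher without SNL replicate 2 (1.44 and 0.48), and the Schwann cell list over single probes (0.78).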

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

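The setting in which outlier spots were kept was chosen after seeing the data, and the other 17 alternatives were planned. A block for slide or scan was not run, since the arrays share 1 slide and 1 scan. No called list and no named called gene turned its direction under any alternative. Of the 50 called genes, 38 to 50 were also called under each alternative to the signal, filter, probe or variance rule, apart from 11 with quantile normalization. Genes higher and lower were 118 and 14 with normexp correction, 11 and 0 with quantile normalization, 97 and 12 with the median of detected probes, 1143 and 88 with no filter on dim probes, and 436 and 123 with a variance trend and robust estimation. Genes lower were 5 with the filter on all 4 arrays and 5 over single probes. The lowest processed signal was 10.9 and 10.4 on the sham arrays and 19.8 and 20.2 on the SNL arrays. The 75th percentiles were 12770 and 12123 against 11828 and 13081. Probes at this floor can thus come out higher in SNL without a change in expression, above all with no filter. The same floor can enlarge fitted rises of genes dim in sham mice and shrink falls of genes dim in SNL mice. At least 2-fold changes at unadjusted p under 0.05 were 1212 higher with no filter, and 94, 95 and 343 lower with normexp correction, the filter on all 4 arrays and single probes. Higher ones made up 84.6%, 83.9% and 82.3% of these with normexp correction, the filter on all 4 arrays and no filter, against 72.8%, 55.4% without SNL replicate 2 and 86.4% without sham replicate 1, and 78.0% of calls with the variance trend, against 94%. Lists higher and lower were 0 and 0 with an estimated correlation and 6 and 0 by fry. The cause was not tested. With 1 mouse left out, the lone mouse of its group is assumed to vary like the other group. Genes higher and lower in limma were then 0 and 0, with 531 to 773 higher and 117 to 557 lower by 2-fold at unadjusted p, and 11 to 22 lists higher and 2 to 8 lower. The replicate numbers did not pair the mice: deviations of same-numbered mice correlated at -0.027 across genes. With the replicate block 0 genes were higher and 0 lower in limma, with 585 higher and 218 lower by 2-fold at unadjusted p, the Schwann cell list was called higher (0.79) and the neutrophil list lower (-0.44), and the pan-neuronal call ended (0.12). These fits leave 1 residual degree of freedom. Removing saturated probes moved nothing, as no spot was saturated. Of 1633 values of named genes under the alternatives, 1397 kept their direction and side of the threshold, 120 lost the call, 114 gained it and 2 reversed. The reversed ones were Gfap at -0.16 with normexp correction and Ckm, which ranged from -0.32 to 5.86 with 1 mouse left out. Of 22 named genes with several detected probes, 1 had probes of opposite sign. Of 720 list values, 593 kept direction and side, 71 lost and 27 gained the call, and 29 turned direction in the test, all in lists not called. Their medians were 0.17 for sensory neurons and 0.22 for ependyma with normexp correction, -0.021 for astrocyte core and -0.43 for B cells with quantile normalization, 0.24 and 0.34 for ependyma with no filter and the filter on all 4 arrays, and -0.11 for B cells over single probes and -0.33 by fry. With 1 mouse left out, medians ranged from 0.044 to 0.19 for astrocyte core, -0.079 to 0.084 for oligodendrocytes, -0.046 to 0.092 for GABA and glycine, -0.057 to 0.10 for ion channels, -0.057 to 0.17 for sensory neurons, -0.26 to 2.04 for Schwann cells and -0.31 to 0.93 for meninges. They ranged from -0.40 to 0.50 for ependyma, -0.81 to 0.11 for B cells, -0.31 to 1.28 for perivascular macrophages, -0.46 to 0.47 for erythroid genes, -1.44 to 3.59 for muscle, -0.071 to 0.030 for cholesterol synthesis, -0.010 to 0.16 for heat shock, -0.070 to 0.11 for caudal and -0.13 to 0.0012 for rostral Hox genes, -0.16 to -0.012 for glutamate transmission and -0.76 to -0.096 for neutrophils and monocytes. The cause was not tested. Signal over background limits the folds of genes that are dim in one group.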

Other observations

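The tests of axon injury and motor neuron genes and of the microglia list were chosen only after the result was seen. Further genes that rose in SNL, chosen after their values were seen, lie outside the fixed lists. Coch, an extracellular matrix gene best known from the inner ear, rose by 3.90 ± 0.12 (SE, adjusted p = 0.0371), and Cd207, which encodes the lectin langerin of antigen-presenting cells, by 3.29 ± 0.14 (adjusted p = 0.0402). The tubulin genes Tubb6 and Tuba1c rose by 2.35 ± 0.12 and 2.12 ± 0.10 (adjusted p = 0.0493 and 0.0475), and Crym, which binds thyroid hormone, by 2.26 ± 0.094 (adjusted p = 0.0402). The serotonin receptor gene Htr2b was not well above background in either sham mouse and was at least 4.86-fold higher in SNL (adjusted p = 0.0475), with a fitted change of 2.62, or 1.56 with normexp correction. Both SNL mice were above both sham mice for each of these genes, as for all 557 genes at least 2-fold higher at unadjusted p under 0.05.

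Genes best known from other tissues, also chosen after their values were seen, are given per mouse. The muscle kinase gene Ckm stood at 1.22 in SNL replicate 1 and at -5.18, -4.11 and -4.96 in the other mice. The albumin gene Alb stood at -0.32 in sham replicate 1 and at -4.73, -5.77 and -5.76 in the others.

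By camera with its preset correlation the axon injury list rose and the motor neuron list fell (adjusted p = 0.472 and 0.501 with an estimated correlation). Over all genes 3 of 27 and 2 of 17 members passed, and 3 of the 17 motor neuron members had values above 0. Dorsal root ganglion tissue carried into the SNL samples is argued against only as far as that tissue still expresses sensory neuron genes. The sensory neuron list had a median log2 change of 0.040 (SD 0.48 over 10 genes), and of 0.030 (SD 0.26) over the 7 members below the 75th percentile in sham mice. Whether a ligated ganglion keeps expressing these genes was not tested here, and a small share of it could be missed. Fewer motor neurons as the whole cause of the falls of Mnx1 and Chodl was not decided. The 17 members of the list had a median of -0.47 (SD 1.38), far from the fall of Chodl, so their falls were uneven. But Chodl is itself a member and was named for its large fall, so a median above it was nearly fixed in advance. The ligation itself and a smaller loss of motor neurons were not tested. These and a larger loss of motor neurons stay open, and slide row cannot be told apart from group.

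By camera with its preset correlation the microglia and macrophage core list rose (adjusted p = 0.472 with an estimated correlation), while 0 of 28 members passed over all genes. Tissue around the cord missing from sham replicate 2 is argued against for this list, because its median was 0.89 without that mouse. It stays open for the reactive astrocyte, complement and antigen presentation lists. Their medians were 0.60, 0.43 and 0.34 with all mice and 0.35, 0.20 and 0.082 without that mouse. For the microglia list, scaling or background correction is argued against by a lowest median of 0.86 over 4 alternatives. Of these, the deposited value table and the median of detected probes mainly shift each array by a constant. The test thus rests on normexp correction and quantile normalization. Blood left in the SNL samples was not decided, as the erythroid list had a median of 0.00153 (SD 0.774 over 9 genes) but 0.47 without sham replicate 2, which lies within that SD of the 0.89. The ligation itself was not tested apart from slide row, and both stay open, as does blood.

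In 3 gene families, 5 of 8 Sprr, 10 of 12 Speer and 2 of 6 Lip genes were at least 2-fold higher at unadjusted p under 0.05. The families were taken up after members stood among the largest increases, so these counts partly follow from that choice. The tests of causes below were set before their results were seen, although a few risen neighbours had been noticed by then. The Sprr and Lip genes lie close together on chromosomes 3 and 19 of mm9, but 7 Speer genes spread from 11344905 to 27826603 on chromosome 5, and 3 of the 17, Speer2, Speer5-ps1 and Speer6-ps1, have no other tested family member on their chromosome. One transcript read by probes of several members cannot be told apart, as 2 of the 17 members, Speer3 and Speer6-ps1, had probes sharing at least 48 of 60 bases with another member's, and transcript sequences were not used here. A rise over whole regions was not decided either, because 152 other genes or named transcripts within 1 Mb had a median of 0.088 but an SD of 1.16. Of these 152, 21 were 2-fold higher at that p, against 557 of all 29114 tested. Families were told apart by gene symbol alone. Predicted genes and region probes beside the Speer genes, with values up to 4.76 on chromosome 5, thus counted as other rows. Some of these may be unnamed family members, which would widen that SD. On chromosome 3, 2310046K23Rik at 4.91 and Lce1g at 2.97 were other rows too and also widen it. Skin carried into the SNL samples stays open too. An epidermis list added after the data were seen had a median of 0.12 (SD 0.45 over 17 genes). In sham mice 4 members lay above the 75th percentile, which would hide a small share, and the 13 below it had a median of 0.16 (SD 0.52). Neither median reached the rise that the test required for skin, but the list left out the risen skin genes Krt16 and Tchhl1. It also left out the risen Sprr genes and the cornified envelope genes Lce1g, Lce1i and Lce1h near them, at 2.97, 1.77 and 1.13. Lce1a2, Lce1l, Lce1m and Lce1c were at 0.41, 0.36, 0.21 and 0.16. These Lce1 genes were named after their values were seen. The ligation itself was not tested apart from slide row.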
